A study of Mus musculus with 2 samples.

How the data were processed

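The series holds 2 GEO samples, a pooled RNA library and a pooled hashtag library, from skin of 8 week old C57BL/6 mice digested with Liberase and DNase. The deposited matrix holds counts, whole-number UMI counts per gene and barcode, which the authors made with Cell Ranger (version not stated) on mm10, with no normalization. Cell calling and annotation are not stated. All 8367 barcodes were in the matrix, with 83725065 UMIs and 8216 of 32285 genes at 0 in every barcode. Barcodes were not assigned to control or depleted skin, because the matrix has no hashtag counts and no condition in its names, and no condition was inferred from expression. The planned comparisons of control against depleted skin, in shares and in expression, and of hashtag counts were therefore not made.

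Barcodes with fewer than 200 genes (87) or more than 20% mitochondrial UMIs (237) were removed, 240 in all, which left 8127. Doublets were called by scrublet as in Scanpy 1.11.5, with an expected rate of 6% and exact neighbours, and 305 (3.75%) were removed. Counts were scaled to 10000 per cell and log transformed, 2000 variable genes among those in at least 3 cells and 30 principal components were taken, and 15 nearest neighbours gave a shared-neighbour graph. Leiden clustering with leidenalg 0.10.2 and igraph 0.11.9 at resolution 1 gave 25 clusters. NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used under Python 3.11.15.

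A cluster took the name of a marker list, with the ending -like, when at least 3 of its markers and at least 50% of the list were 2-fold above the median cluster with a UMI in at least 10% of its cells. Among lists that qualified, the one with the most markers among the 10 leading genes was chosen. A cluster with a median below the sample median divided by 3 and no marker among its leading genes stayed unnamed. This gave 14 named classes from 25 marker lists. The T cell-like, gamma-delta T cell-like and NK or innate lymphoid-like classes were also merged as lymphoid-like, and the 3 keratinocyte classes as keratinocyte-like. Markers and leading genes of a class were not read as results for it.

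UMIs were summed per class and given as CPM with exact Poisson intervals. A fold between classes is the ratio of these rates with its exact conditional interval, and a share of cells has a Clopper-Pearson interval. A count of 0 was read as up to 3 counts. The 23 gene lists were matrix, TGF-beta, neutrophil, cytokine, interferon, barrier, junction, antigen presentation, stress, proliferation, hypoxia and erythrocyte lists. For each list and class, the median log2 ratio of the class over all other cells, with 0.5 UMIs added to each count, was placed among 10000 random lists of the same size, matched in 20 bins of total UMIs. List members and random genes needed 50 UMIs, which 15285 genes had, and 4 list symbols had no row in the matrix. No p-value was computed, since cells are not replicates. Shares of cells with a UMI were computed after thinning each cell to 1000 UMIs. Gene positions are from the GENCODE annotation of mm10.

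Genes were named by a rule fixed before the files were opened: for each list and class, the 3 members with the highest CPM and the 3 with the largest log2 ratio among members with at least 20 UMIs in the class, and Ly6g. On simulated counts with known folds, the method gave a median of 3.97 for 4-fold and 0.245 for 0.25-fold in fibroblast-like cells, and 90% to 98% of intervals held the true fold. In neutrophil-like cells it gave 4.05 for 4-fold, over the 21 genes of 50 with at least 20 UMIs. For 0.5-fold it gave 0.591 there, over 2 genes of 50. The simulated counts were Poisson draws of class totals without variation between barcodes. They check the calculation and cannot show how intervals hold where a few barcodes carry most UMIs of a gene. A simulated list raised 2-fold came to percentile 100 in the 3 classes tried. Of 21 unchanged lists, 1 in neutrophil-like and 0 in fibroblast-like or macrophage-like cells fell outside the percentiles.

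Alternatives were 500 genes per cell, 10% mitochondrial UMIs, doublets kept, Leiden resolution 0.5 or 2, every cell weighing the same, cells with 2 or more fibroblast markers left out, and expected free RNA subtracted. Further alternatives, without barcodes with 10 or more Dcn UMIs in the neutrophil-like class alone or in every class but fibroblast-like, without the cells of cycling cluster 15, and without the 10 neutrophil-like barcodes with more UMIs, were chosen after seeing the data.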

Results

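The transcriptome of dissociated mouse skin was measured by droplet single-cell RNA sequencing, in C57BL/6 animals of 8 weeks. Neutrophils had been depleted with an antibody against Ly6G, clone 1A8, on 2 consecutive days at steady state, and the question of the series is what this depletion changes in the skin. Cells of control and depleted skin carried hashtag antibodies and were pooled. The count matrix held 1 pooled RNA library with 8367 barcodes, 32285 genes and 83725065 unique molecular identifiers (UMIs). It had 0 rows of hashtag counts, and no barcode name carried a condition. Control and depleted cells were therefore not compared, the hashtag library was not used here, and every value below describes the pool. A barcode held at least 500 UMIs, with a median of 9426 UMIs and 2872 genes. After the filters and the removal of 305 called doublets, 7822 cells with 78506260 UMIs remained, with a median of 9531.5 UMIs. There was 1 library and no replicate, so intervals are 95% intervals, exact Poisson for UMIs and Clopper-Pearson for shares. They cover counting error only.

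The first comparison was of the cell classes that make up the pool. Fibroblast-like cells, named by Dcn, Lum and collagen I, were the most frequent class, with 3952 cells or 50.5% (49.4 to 51.6). Keratinocyte-like cells, the keratin-producing cells of the epidermis and hair follicle, made up 16.9% (16.1 to 17.7), and macrophage-like cells, the resident phagocytes, 15.9% (15.1 to 16.7). Lymphoid-like cells together held 4.47% (4.03 to 4.96). Neutrophil-like cells, the type the antibody is directed at, were 40 cells or 0.511% (0.366 to 0.696). Ly6g, the antibody's target, a membrane protein of neutrophils, had 2 UMIs in all 8367 barcodes and 1 UMI in the neutrophil-like class, which is 4.75 CPM (0.120 to 26.5), where CPM is the count scaled by the UMI total of the class. Ly6g lies on chromosome 15 at 75155240 to 75159126, plus strand, on the mm10 assembly.

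Among the keratinocyte-like cells, 615 were basal, 415 suprabasal and 291 hair follicle-like. The other myeloid classes were dendritic-like cells with 240 cells or 3.07% (2.70 to 3.47), monocyte-like cells with 236 cells or 3.02% (2.65 to 3.42) and mast-like cells with 23 cells or 0.294% (0.186 to 0.441). T cell-like cells numbered 200, natural killer (NK) or innate lymphoid-like cells 99 and gamma-delta T cell-like cells 51. The class of skeletal muscle-like cells held 97 cells, and that of pericyte or smooth muscle-like cells 18. Blood endothelial, lymphatic endothelial, Schwann, melanocyte, B cell, basophil, eosinophil, sebocyte, adipocyte and Langerhans markers led to no named cluster. Of the blood endothelial markers Pecam1 had 1889, Kdr 1214, Flt1 383 and Cdh5 49 UMIs in all cells analysed, and 13 cells held 3 or more of the 6 markers. Clusters 10 and 19, with 302 cells together, stayed unnamed because of low UMI counts. No sort or gate is stated, so these shares describe what the digestion released and the droplets captured.

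Cluster genes outside the marker lists are given so that the names can be read with them. Cycling genes such as Mki67 and Top2a led macrophage-like cluster 15, with 184 cells, and basal keratinocyte-like cluster 21, with 44 cells. The cytokine genes Il5, Areg and Csf2 were among the leading genes of the T cell-like cluster. Pecam1, an endothelial gene, was among those of fibroblast-like cluster 3. Lyve1, from the lymphatic endothelial marker list, was among those of macrophage-like cluster 8, beside the macrophage markers C1qa and C1qc. The names rest on marker lists alone. The T cell-like class was not named under 3 alternatives, in which NK or innate lymphoid-like cells made up 2.71%, 2.78% or 3.82% in place of 1.27%. Of the 200 T cell-like barcodes, 86 took the macrophage-like name with 500 genes per cell, 88 with 10% mitochondrial UMIs, 79 with doublets kept and 79 at resolution 2. The NK or innate lymphoid-like name went to 111, 112 and 118 under the first 3 of these and to all 200 at resolution 0.5. The T cell-like and lymphoid-like values include all 200.

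**Figure D1:**
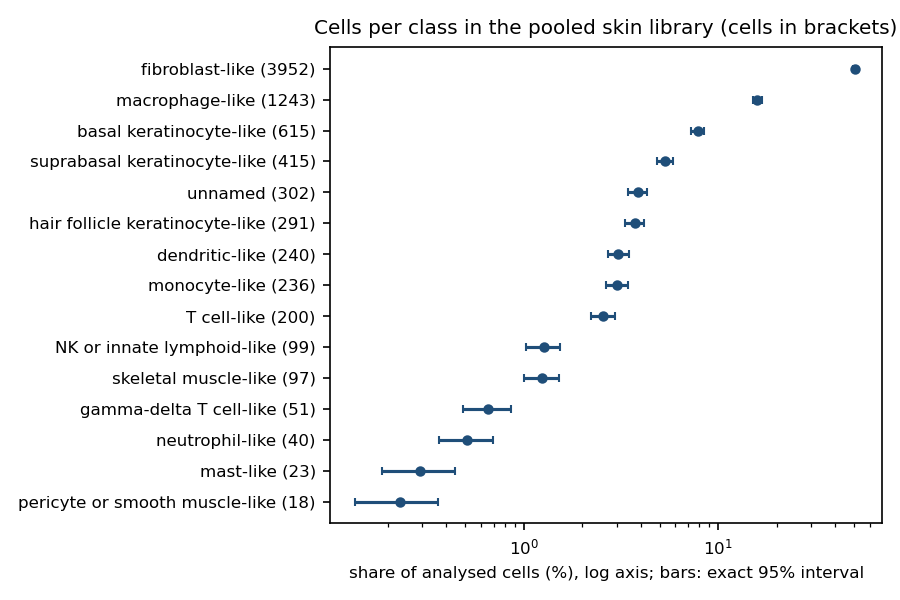
Share of the 7822 analysed cells in each class, in percent on a log axis, with exact 95% intervals as bars and cell numbers in brackets. Fibroblast-like cells hold 50.5% and neutrophil-like cells 0.511%.

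The next comparison was of the 23 fixed gene lists across classes, each class against all other cells. In fibroblast-like cells the matrix genes stood together. Of the fibrillar collagens outside the markers, 6 of 7 were more than 2-fold above the other cells, with a median log2 ratio of 5.70. Col3a1, the chain of type III collagen, reached 4749 CPM (4728 to 4769) against 65.2 CPM in the other cells. Other collagens had 10 of 12 members and basement membrane genes 14 of 24 members above 2-fold. Among them were Col6a3 at 783 CPM, Nid1 at 1016 CPM and Lama2 at 584 CPM, which code for a microfibril collagen, the basement membrane linker nidogen and a laminin chain. The glycoproteins Sparc and Fbn1, a collagen-binding protein and the fibrillin of elastic fibres, were at 2745 and 1330 CPM. Of the assembly and crosslinking genes, 17 of 23 were above 2-fold, including Serpinh1, the collagen chaperone, at 1150 CPM and Lox, which crosslinks collagen, at 147 CPM. The protease and inhibitor list had 14 of 24 members above 2-fold, among them the inhibitor Timp2 at 2629 CPM and the aggrecanase Adamts5 at 652 CPM.

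Fibroblast-like cells also held some immune signalling genes. In the interferon-stimulated list 8 of 14 members were above 2-fold, with Cxcl10, a chemokine that attracts T cells, at 377 CPM, 5.27-fold (5.06 to 5.50). In the TGF-beta pathway 10 of 21 members were above 2-fold, with the receptors Tgfbr2 at 748 CPM and Tgfbr3 at 542 CPM. Of the neutrophil chemoattractants and growth factors 3 of 10 were above and 6 below 2-fold. Those above were Cxcl1, a neutrophil chemokine, at 936 CPM and 15.5-fold (14.8 to 16.2), Cxcl12, the ligand of Cxcr4, at 193 CPM, and Ptgs2, the inducible cyclooxygenase, at 483 CPM. The cytokine Il6 was at 186 CPM, 6.56-fold (6.14 to 7.02), but 2 of 15 inflammatory cytokines were above and 9 below 2-fold. The medians of these cytokines and of the chemoattractants, −2.86 and −1.56, were below the lower percentile.

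Macrophage-like cells carried antigen presentation genes, with 8 of 11 members above 2-fold. Cd74, the invariant chain of MHC class II, was at 11168 CPM and H2-Ab1, a class II chain, at 5020 CPM. Chemoattractants had 5 of 10 members above 2-fold, with Cxcl2, a ligand of Cxcr2, at 1605 CPM, 10.7-fold (10.4 to 10.9), and Alox5ap, needed for leukotriene synthesis, at 827 CPM. Inflammatory cytokines had 6 of 15 above, among them Il1b at 567 CPM and its antagonist Il1rn at 124 CPM. Proliferation genes outside the leading ones were above 2-fold in 10 of 10 cases, with a median of 2.04. Without cycling cluster 15, a choice made after seeing the data, 4 of 10 were, with a median of −0.061, and the chemoattractants fell to percentile 94.98. Matrix proteases had 6 of 25 members above and 15 below 2-fold, and those above included the cathepsin Ctss at 972 CPM, 13.6-fold (13.2 to 14.1). Nrros, which tethers latent TGF-beta on myeloid cells, was at 261 CPM.

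Monocyte-like cells were above the upper percentile for 4 lists: antigen presentation, neutrophil granule proteins, neutrophil ageing and trafficking, and interferon-stimulated genes. Cybb, the oxidase subunit, was at 1131 CPM, 9.62-fold (9.15 to 10.1). Rsad2, an antiviral interferon target, was at 206 CPM. Neutrophil-like cells were above it for 5 lists: those 4 and the chemoattractants, whose call ended with 500 genes per cell (percentile 96.7) and with equal weights (percentile 97.49). Il1b reached 3214 CPM (2976 to 3465) in them, 19.3-fold (17.8 to 20.8) over all other cells. Il1b was also among the leading genes of the dendritic-like cluster. In dendritic-like and monocyte-like cells it had the highest CPM of the inflammatory cytokine list. Lcn2, a siderophore-binding granule protein, was at 357 CPM, 297-fold (216 to 407). The glucose transporter Slc2a3 was at 404 CPM, 61.1-fold (48.0 to 77.0). These sums rest on unlike barcodes, since 10 of the 40 held 9604 to 21341 UMIs each, 64.3% of the class, and the other 30 held at most 4928. Neutrophil markers were at 12341 CPM in the 10 and 62221 CPM in the 30, macrophage markers at 3847 and 918 CPM, and monocyte markers at 3796 and 333 CPM. Macrophage markers were at 5049 CPM in macrophage-like cells and monocyte markers at 7343 CPM in monocyte-like cells. Of the 10 barcodes, 7 held 3 or more macrophage markers and 5 held 3 or more monocyte markers. Fibroblast markers were at 3107 CPM in the 10 and 93.1 CPM in the 30. Of the 10, 4 held 3 or more fibroblast markers, 1 basal keratinocyte and 1 hair follicle markers, against 0, 1 and 0 of the 30. Sums over all 40 barcodes may therefore include RNA of other cells, myeloid or not, which was not tested. Without the 10, a choice made after seeing the data, Il1b was at 6039 CPM, Lcn2 at 811 CPM and Slc2a3 at 878 CPM. The antigen presentation call then ended, with a median of −0.67 in place of 0.84, and so did the interferon call, with 0.0091 in place of 0.91. Inflammatory cytokines and hypoxia genes were above the upper percentile there, with medians of 1.26 and 1.16. The 2 neutrophil-like barcodes with fibroblast RNA, described with the matrix genes and part of the 10, were enough to end the interferon call. Without them in this class its median log2 ratio was 0.0068, at percentile 81.2, and 4 lists were above the upper percentile. The medians of granule proteins and chemoattractants were 1.88 and 0.79, or 2.15 and 1.29 with members at 0 set to their bound. Of the 11 antigen presentation genes 0 were above 2-fold in neutrophil-like cells, and their median was −0.075 when every cell weighed the same.

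After thinning each cell to 1000 UMIs, Il1b had a UMI in 81.6% of 38 neutrophil-like cells (65.7 to 92.3) and in 23.3% of macrophage-like cells. In fibroblast-like cells, taken as the class without the gene, the share was 0.331%. Without thinning these shares were 100%, 44.1% and 2.58%, at median depths of 2782.5, 9983 and 10696 UMIs. Barcodes under 1000 UMIs, 2 of the neutrophil-like ones, were left out of the thinned shares.

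The 3 keratinocyte-like classes were set apart by junction genes, and suprabasal cells also by barrier genes. Cell junction members were above 2-fold in 11 of 13 cases in basal, 12 of 14 in suprabasal and 12 of 14 in hair follicle-like cells. Dsp, the desmosomal plaque protein, was at 653 CPM in basal and 1209 CPM in suprabasal cells. The laminin chains Lama3 and Lamb3 of the epidermal basement membrane were at 185 and 173 CPM in basal cells, 20.9-fold (18.96 to 23.0) and 16.1-fold (14.7 to 17.6), while the basement membrane list had 9 members above and 13 below 2-fold there, with a median of −3.07. In suprabasal cells, cornified envelope and barrier genes outside the markers were above 2-fold in 8 of 9 cases, while the list was at percentiles 83.0 and 24.3 in basal and hair follicle-like cells. Abca12, a lipid transporter of the skin barrier, was at 201 CPM and 34.0-fold (30.3 to 38.1), and Klk5, a protease of desquamation, at 25.0 CPM and 307-fold (137 to 853). Dissociation stress genes were above the upper percentile in basal and hair follicle-like cells, with medians of 0.48 and 0.34. Atf3, an early stress gene, was at 3217 CPM in basal cells.

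Smaller classes each had a short set of genes. T cell-like cells held Il13, a type 2 cytokine, at 202 CPM (177 to 228) against 0.155 CPM elsewhere, and Il17a, which drives neutrophil recruitment, with 31 UMIs against 0 in all other cells. NK or innate lymphoid-like cells held Ccl4 and Ccl3, chemokines for myeloid cells, at 2304 and 599 CPM. Gamma-delta T cell-like cells held Col27a1, a fibrillar collagen, at 475 CPM, 71.3-fold (57.9 to 87.2), while 0 of the 22 lists were above the upper percentile in them. Mast-like cells held the type 2 cytokine Il4 at 595 CPM (412 to 831) and Serpinb1a, an inhibitor of neutrophil proteases, at 2850 CPM. In the same class 11 of 15 dissociation stress genes were above 2-fold, with Jun at 6382 CPM. Dendritic-like cells held Cd74 at 21842 CPM. Pericyte or smooth muscle-like cells held Timp4, a protease inhibitor, at 258 CPM and the stress gene Nr4a1 at 1549 CPM. In skeletal muscle-like cells the glycolytic gene Ldha was at 2491 CPM, 13.1-fold (12.4 to 13.8).

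Of 330 pairs of list and class, 42 had a median above percentile 97.5 of 10000 random lists matched on UMIs and 190 had one below percentile 2.5. Fibroblast-like cells gave 10 lists above and 11 below, macrophage-like cells 5 and 13, and neutrophil-like cells 5 and 8. Fibroblast activation genes were above 2-fold in 8 of 11 cases in fibroblast-like cells. Hypoxia and glycolysis genes were above the upper percentile in mast-like cells, with a median of 0.79, but at percentiles 93.3 to 95.5 under 4 alternatives. Antigen presentation was also above it in NK or innate lymphoid-like and dendritic-like cells, with medians of 0.81 and 1.49, 3 and 7 of 11 members above and 5 and 0 below 2-fold. The Ly6 family and the antimicrobial peptides were above it in 0 of the 15 classes. In neutrophil-like cells 3 of the 10 measured antimicrobial members, S100a8, S100a9 and Slpi, were left out as markers or leading genes. S100a8 had 2038 and S100a9 2963 UMIs in that class. Ly6g, with 1 UMI in the cells analysed, had too few UMIs to be a measured member of its list. The list of erythrocyte RNA had fewer than 3 measured members and was not tested. The percentiles describe position and are not tests, because cells of 1 library are not replicates. In T cell-like cells inflammatory cytokines, antigen presentation and proliferation were above it, with medians of 0.61, 0.45 and 0.41. With equal weights these were −0.16, 0.14 and 0.097, and 0 lists were above it. With doublets kept the name moved to other cells, 51 of 60 from the gamma-delta class, so its medians there describe another class.

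**Figure D2:**
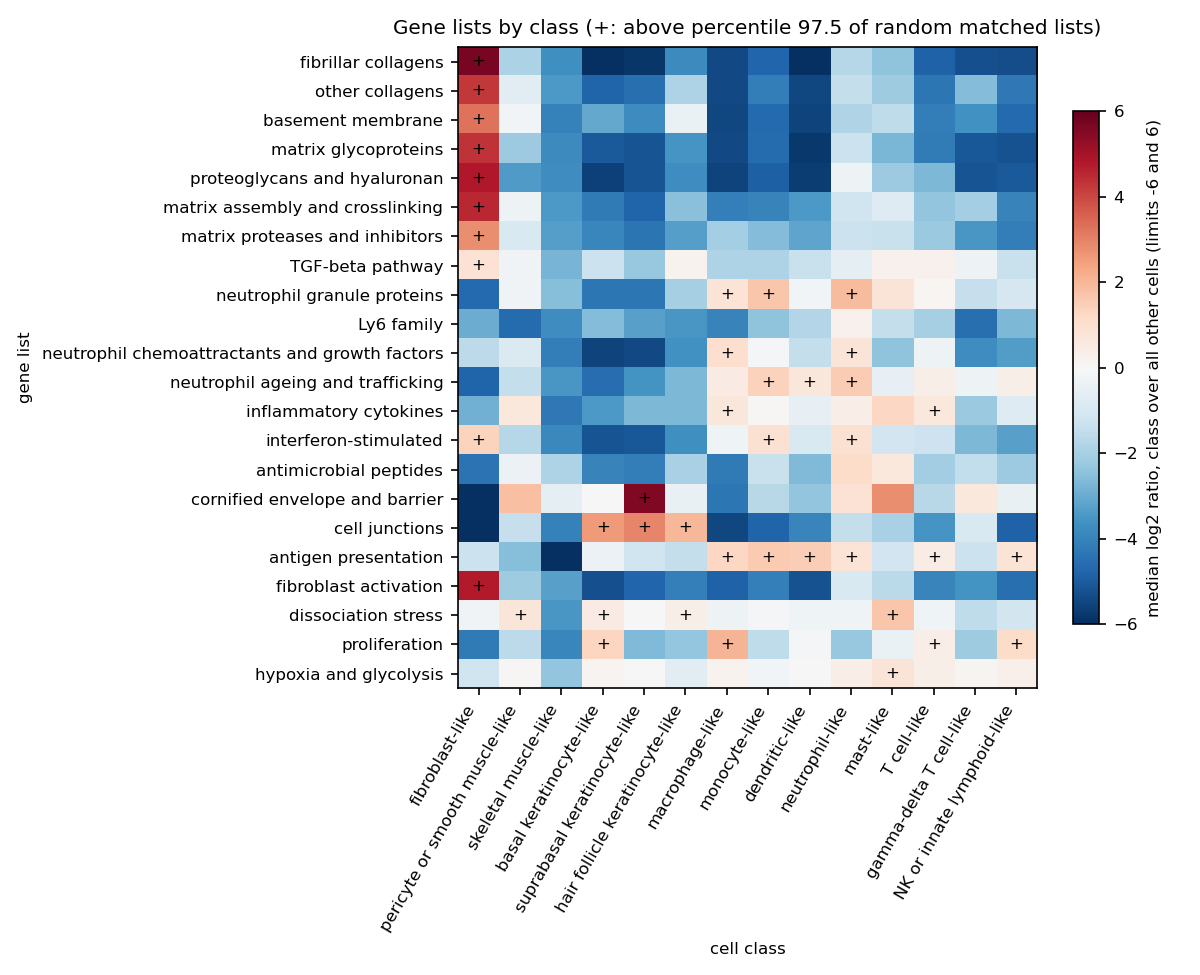
Median log2 ratio of each fixed gene list in each named class over all other cells, with a plus sign where the median is above percentile 97.5 of random matched lists. The 7 matrix lists stand above it in fibroblast-like cells and in no other named class, while the interferon-stimulated list in neutrophil-like cells falls to percentile 81.2 without 2 barcodes and the antigen presentation list there to percentile 74.0 without 10.

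The last comparison asked which matrix genes neutrophil-like cells carry, since the series concerns what the loss of these cells changes in skin. Neutrophil-like cells held Thbs1, Srgn, Cd44, Emilin2 and Tgm2 above macrophage-like cells. Thbs1, thrombospondin 1, an adhesive glycoprotein that activates latent TGF-beta, was at 1559 CPM (1395 to 1738). That is 16.7-fold (14.7 to 18.8) macrophage-like cells and 56.0-fold (42.1 to 75.8) lymphoid-like cells. Srgn, serglycin, the granule proteoglycan, was at 4921 CPM, 4.85-fold (4.55 to 5.16) macrophage-like cells. Cd44, the hyaluronan receptor, was at 1212 CPM, 2.07-fold (1.82 to 2.34) macrophage-like cells. With barcodes of 10 or more Dcn UMIs left out on both sides, Srgn was 2.85-fold (2.66 to 3.06) and Cd44 2.24-fold (1.94 to 2.57) lymphoid-like cells. Srgn also had the largest ratio of its list in T cell-like, monocyte-like, dendritic-like and mast-like cells. Emilin2, an elastin-associated glycoprotein, was 2.71-fold (2.13 to 3.39) and Tgm2, a protein crosslinking enzyme, 36.8-fold (23.0 to 57.8) macrophage-like cells. In the 30 barcodes with fewer UMIs, against all macrophage-like cells, Thbs1 was at 3219 CPM and 34.4-fold (29.8 to 39.5), Srgn 9.54-fold, Cd44 3.74-fold, Emilin2 3.83-fold and Tgm2 80.4-fold. In the 10 with more, Thbs1 was at 636 CPM (509 to 786). Thbs1 lies on chromosome 2 at 118111876 to 118127133, plus strand, and Srgn on chromosome 10 at 62493833 to 62527451, minus strand.

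As lists, 6 of the 7 sets of matrix genes were below the lower percentile in neutrophil-like cells. The other cells include the fibroblast-like ones, and the fibrillar collagen median was −5.40 in macrophage-like against −1.73 in neutrophil-like cells. Matrix proteases had 4 of 24 members above and 14 below 2-fold over all other cells, with a median of −1.29. With counts under 3 set to 3 this median was −0.44. In the 30 barcodes with fewer UMIs, proteases were at percentile 12.2 and no longer below. Proteoglycans and hyaluronan genes, the list not below, fell there from percentile 44.6 to 0.03. Their median there was −3.27, but −0.86 with counts under 3 set to 3, since these barcodes held 75184 UMIs in all. Mmp8, neutrophil collagenase, was at 133 CPM (88.5 to 192) against 2 UMIs in macrophage-like cells, a ratio of 901 (227 to 7805). The membrane protease Adam8 was at 433 CPM, 3.53-fold (2.83 to 4.37) macrophage-like cells. The gelatinase Mmp9, 442 CPM, is a marker of the class. The cathepsins Ctsb and Ctss were at 0.608-fold (0.514 to 0.715) and 0.648-fold (0.534 to 0.779) macrophage-like cells once 2 barcodes with fibroblast RNA, described next, were left out of the neutrophil-like class alone, and at 0.267-fold (0.176 to 0.389) and 0.219-fold (0.125 to 0.356) in the 30 barcodes with fewer UMIs. Fn1, fibronectin, chosen after its values were seen, was at 0.178-fold (0.141 to 0.222) macrophage-like cells in all 40 barcodes. Without the 2 barcodes, which held 32 of its 78 UMIs, Fn1 was at 0.122-fold (0.0892 to 0.163). In the 30 barcodes with fewer UMIs, Fn1 had 8 UMIs or 106 CPM (45.9 to 210), against 70 UMIs or 518 CPM (404 to 654) in those with more. Macrophage-like cells, with those holding 2 or more fibroblast markers left out, had Fn1 at 2078 CPM.

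Fibrillar collagens summed to 366 UMIs or 1740 CPM in neutrophil-like cells, 12.8-fold (11.5 to 14.4) macrophage-like, 7.46-fold (6.49 to 8.57) lymphoid-like and 0.136-fold (0.122 to 0.151) fibroblast-like cells. Of these UMIs 352, or 96.2%, lay in 2 of the 40 barcodes, which also held 186 of the 195 UMIs of Dcn and all 21 UMIs of Lum. Without these 2 barcodes, a split chosen after seeing the data, 14 UMIs or 77.3 CPM were left, 0.571-fold macrophage-like and 0.331-fold lymphoid-like cells, which kept all their barcodes. With barcodes of 10 or more Dcn UMIs left out of those classes too, 18 macrophage-like and 6 lymphoid-like ones, the folds were 0.949 (0.517 to 1.60) and 0.593 (0.319 to 1.01). Leaving out barcodes with 2 or more fibroblast markers on both sides, as planned, gave 0.760-fold (0.346 to 1.45) and 0.475-fold (0.215 to 0.917). Col3a1, on chromosome 1 at 45311538 to 45349706, plus strand, had 182 of its 187 UMIs in the 2 barcodes. Thbs1 had 1 of its 328 UMIs there and a UMI in 36 of the other 38, and its fold over macrophage-like cells without them was 19.3 (17.0 to 21.8).

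Lists differed in what the 2 barcodes carried. Over all macrophage-like cells, other collagens were 10.1-fold (7.75 to 12.9) with the 2 barcodes and 1.30-fold (0.558 to 2.58) without them, and basement membrane genes 7.11-fold (5.76 to 8.68) and 2.39-fold (1.62 to 3.42). The planned removal on both sides gave 1.09-fold (0.223 to 3.22) for other collagens and 1.49-fold (0.767 to 2.63) for basement membrane genes. Of the 31 basement membrane UMIs left without the 2 barcodes, 13 were of Col17a1, the hemidesmosomal collagen and a basal keratinocyte marker, and 2 of these remained after the planned removal. Krt14, another marker of basal keratinocytes, had a UMI in 2.63% of thinned neutrophil-like and 1.62% of macrophage-like cells. Without thinning these shares were 5% and 10.4%, at medians of 2782.5 and 9983 UMIs. Such shares do not show how UMIs spread over barcodes. Markers of basal keratinocytes, Col17a1 and Krt14 among them, summed to 87 UMIs or 644 CPM (516 to 794) in the 10 neutrophil-like barcodes with more UMIs. In the 30 with fewer they summed to 10 UMIs or 133 CPM (63.8 to 245). Assembly genes were 2.06-fold (1.78 to 2.37) with and 1.01-fold (0.810 to 1.25) without the 2 barcodes. Glycoproteins were 1.42-fold (1.34 to 1.52) and 1.02-fold (0.942 to 1.11), and proteases 1.20-fold (1.13 to 1.29) and 1.03-fold (0.956 to 1.11). Proteoglycans and hyaluronan genes were 4.27-fold (4.05 to 4.49) and 3.91-fold (3.69 to 4.14), with most UMIs from Srgn. TGF-beta pathway genes were 1.10-fold (0.956 to 1.26) and 0.988-fold (0.843 to 1.15).

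After thinning to 1000 UMIs, Thbs1 had a UMI in 68.4% of neutrophil-like cells (51.3 to 82.5), 32.5% of monocyte-like, 4.77% of macrophage-like and 1.16% of lymphoid-like cells. Without thinning the shares were 92.5%, 50.4%, 17.6% and 4.57%, at median depths of 2782.5, 6935.5, 9983 and 4745 UMIs. Basal keratinocyte-like cells also held Thbs1, in 22.4% of thinned cells and 53.3% of cells without thinning at a median of 10926 UMIs. Col3a1 had a UMI in 10.5% of thinned neutrophil-like cells (2.94 to 24.8), which is 4 cells, and in 2 of 36 or 5.56% (0.680 to 18.7) without the 2 barcodes, against 5.01% of macrophage-like, 4.35% of lymphoid-like and 86.0% of fibroblast-like cells. Without thinning the Col3a1 shares were 17.5%, 27.0%, 17.4% and 95.8%, the last at a median of 10696 UMIs. Without the 2 barcodes, the Col3a1 interval of 0.680% to 18.7% held the thinned shares of macrophage-like and lymphoid-like cells. No clear excess over them was seen, and one within that interval cannot be excluded. With 210344 UMIs in the class, a count of 0 allows up to 14.3 CPM.

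**Figure D3:**
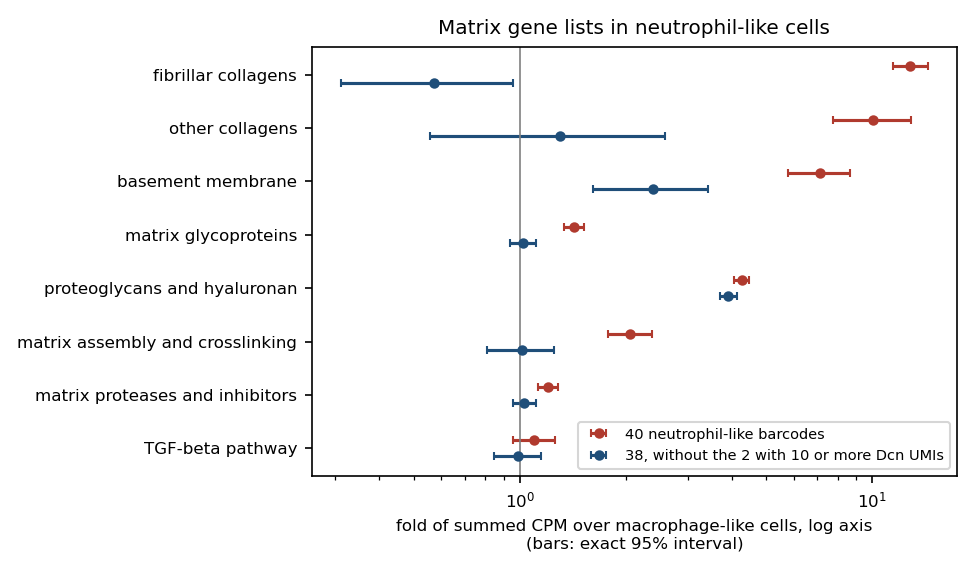
Fold of the summed CPM of each matrix list in neutrophil-like over macrophage-like cells on a log axis, with exact 95% intervals, for all 40 barcodes and for the 38 without those with 10 or more Dcn UMIs, over all macrophage-like cells. Fibrillar collagens move from 12.8-fold to 0.571-fold, and proteoglycans and hyaluronan from 4.27-fold to 3.91-fold.

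**Figure D4:**
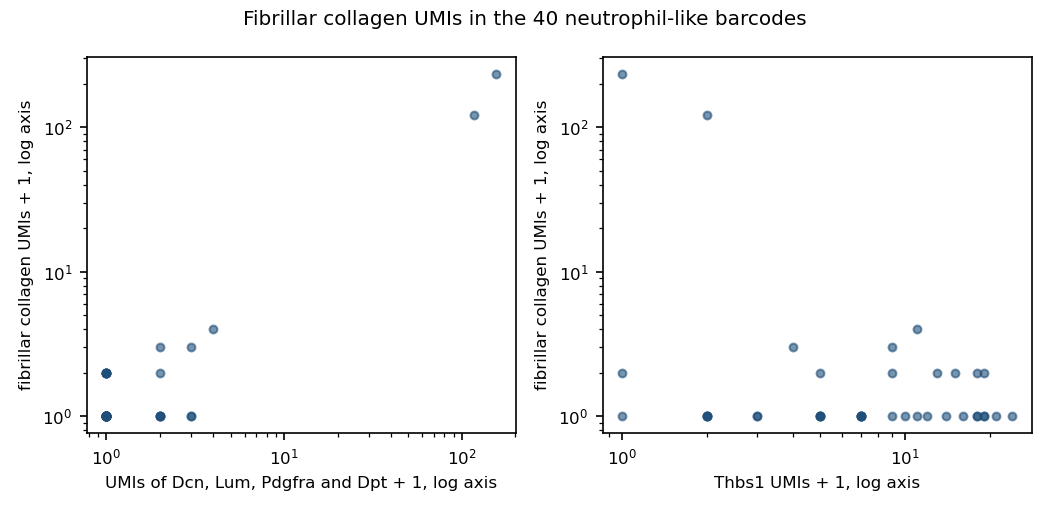
UMIs of fibrillar collagens in each of the 40 neutrophil-like barcodes against the UMIs of Dcn, Lum, Pdgfra and Dpt and against the UMIs of Thbs1, with 1 added to each count and log axes. The 2 barcodes with 352 collagen UMIs hold 1 Thbs1 UMI.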

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

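All tests in this part were chosen after the results were seen. The gene lists, marker lists and filters were chosen before the data were examined.

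Barcodes outside the cells analysed held signals that the comparisons do not use. The 240 barcodes removed by the filters held 8537 UMIs of the erythrocyte markers, 32269 CPM against 2.61 CPM in the cells analysed, and 3 of them had 945, 3057 and 4745 UMIs from 20, 47 and 62 genes, with 97.4% to 97.8% erythrocyte UMIs. The 305 called doublets held 2068 UMIs of the B cell markers, 417 CPM against 4.41 CPM in the cells analysed, and 5 of them showed 3 or more of these markers. Of these UMIs 1990 lay in 3 barcodes, and 1973 of those were of Jchain. The 3 barcodes also held 830, 2336 and 3693 UMIs of the immunoglobulin gene Igkc, but 1, 0 and 2 of Cd79a. Which cells they came from was not tested. The same 305 barcodes held 1111 UMIs of the neutrophil markers, 224 CPM against 282 CPM in the cells analysed, with 3 barcodes that showed 3 or more of them.

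The fibrillar collagen UMIs of the neutrophil-like class sat in 2 barcodes, with 96.2% of them against 13.9% of all UMIs of the class, which argues against free RNA spread over every droplet. The 2 barcodes were picked by their UMIs of Dcn, a fibroblast marker, and 50 fibroblast genes were ranked in the same matrix. Some rise of these genes was therefore likely from the selection. In the 2 barcodes the 50 genes, all outside the lists, stood at 64.1% of the fibroblast-like level, against 0.397% in the other 38 and 0.863% in macrophage-like cells. This is consistent with barcodes that hold a neutrophil and a fibroblast, and argues against expression by the neutrophils themselves as the whole source. Both barcodes showed 7 of the 8 neutrophil markers but 1 Thbs1 UMI together, so the kind of neutrophil in them stays open.

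In the other 38 barcodes 14 fibrillar collagen UMIs were left. With barcodes of 10 or more Dcn UMIs left out on both sides, they were 0.949-fold (0.517 to 1.60) macrophage-like and 0.593-fold (0.319 to 1.01) lymphoid-like cells. Whether they are free RNA or expression by the neutrophils stays open. No biological difference between groups was tested, since the pool has no condition for each cell.

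Unnamed cluster 10, with 240 cells and a median of 1775.5 UMIs, had a mitochondrial share of 8.58%, 3.36-fold that of macrophage-like cells, and a share of ribosomal protein mRNA of 3.34% against 16.6%. These values are consistent with damaged cells that lost cytoplasmic RNA, while the mitochondrial share argues against nuclei without cytoplasm. Malat1, a nuclear RNA, was at 2.93% of UMIs against 0.408%, so nuclei with some cytoplasm attached stay open. Fibrillar collagens were at 0.0503-fold their share in all cells but at 0.0361% against 0.0135% in macrophage-like cells, and with no barcodes without a cell in the matrix, droplets with free RNA alone cannot be told apart from damaged cells. Of the 7 macrophage markers Mrc1 and Adgre1 were at 1.15-fold and 1.10-fold macrophage-like cells and the other 5 at 0.217-fold to 0.494-fold, and no biological explanation was tested.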

How the results depend on the processing

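The alternatives without barcodes with 10 or more Dcn UMIs, in the neutrophil-like class alone or in every class but fibroblast-like, without cycling cluster 15, and without the 10 neutrophil-like barcodes with more UMIs were chosen after the result was seen, and the others were planned. Of 1376 comparisons of list medians past a percentile, 1310 kept sign and side, 49 kept the sign only and 17 changed sign. Of 178 comparisons of list counts per class, 171 stayed within 1.5 times, and of 264 matrix folds, 136 stayed within their interval, 112 moved and 16 reversed. Neutrophil-like cells numbered 38 to 41 over filters and resolutions. Of 81 comparisons of shares 60 stayed within the interval. With 500 genes per cell the shares outside it were NK or innate lymphoid-like 2.71%, macrophage-like 17.0%, unnamed 3.44% and lymphoid-like 3.37%; with 10% mitochondrial UMIs 2.78%, 17.5%, 1.48% and 3.45%. With doublets kept they were 2.89%, 17.5%, 3.38% and 3.63%, and T cell-like 0.738%. At resolution 0.5 they were NK or innate lymphoid-like 3.82%, macrophage-like 18.98% and unnamed 0.793%, and at resolution 2 fibroblast-like 47.2%, macrophage-like 18.3%, T cell-like 1.55%, unnamed 5.74% and lymphoid-like 3.46%. The T cell-like class was absent with 500 genes, 10% mitochondrial UMIs or resolution 0.5, and the gamma-delta class with doublets kept, so these gave no value. Reversed medians in NK or innate lymphoid-like cells were chemoattractants at 0.41 (500 genes), 0.39 (10% mitochondrial), 0.52 (doublets kept) and 0.70 (resolution 0.5), and TGF-beta at 0.0090 (resolution 0.5), where the name covered 111, 112, 118 and 200 barcodes that were T cell-like in the main setting. Cell junctions reversed in mast-like cells at 0.11 (500 genes) and 0.18 (10% mitochondrial) and in unnamed cells at −3.20 (10% mitochondrial) and −0.058 (resolution 2). With doublets kept, T cell-like medians reversed for inflammatory cytokines (−0.44), cornified envelope (0.089), antigen presentation (−0.20) and proliferation (−1.47), but 51 of the 60 cells with this name were gamma-delta T cell-like and 3 T cell-like in the main setting, so the name moved. With every cell weighing the same, inflammatory cytokines in T cell-like (−0.16) and antigen presentation in neutrophil-like cells (−0.075) reversed. Without the barcodes with Dcn, the interferon median in neutrophil-like cells was 0.0068, no longer past the percentile. Without the 10 barcodes with more UMIs it was 0.0091, also not past it, and antigen presentation in neutrophil-like cells reversed at −0.67. Without cycling cluster 15, the proliferation median in macrophage-like cells reversed at −0.061, chemoattractants were no longer past the percentile, and 3 lists were above it in place of 5. The fibrillar collagen fold over macrophage-like cells was 14.6 with 500 genes, 14.97 with 10% mitochondrial UMIs, 4.71 with doublets kept, 4.75 with equal weights, 40.5 with free RNA subtracted, 0.760 without cells with 2 or more fibroblast markers 0.571 without the 2 barcodes, 0.491 without the 10 and 0.949 with barcodes with Dcn left out on both sides. Over lymphoid-like cells it was 6.44 with 10% mitochondrial UMIs, 0.897 with doublets kept, 8.95 at resolution 2, 3.19 with equal weights, 11.1 with free RNA subtracted, and 0.475, 0.331, 0.285 and 0.593 under the last 4 alternatives. Over fibroblast-like cells it was 0.0522 with equal weights, 0.00484 without fibroblast markers, 0.00520 without the 10 barcodes and 0.00604 without the barcodes with Dcn, on one side or both. Basement membrane over lymphoid-like cells reversed at 0.955 (doublets kept), 0.502, 0.854 and 0.730, and other collagens at 0.585, 0.759 and 0.686 (without fibroblast markers, then without the 2 barcodes, then without the 10). Apart from the barcodes left out by construction and the names that moved, the cause was not tested. The alternatives set out for control against depleted skin and for hashtag counts were not run. Depth limits the neutrophil-like class, where a count of 0 allows 14.3 CPM.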

Other observations

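All values in this part were picked after the results were seen, and no test was run on them. The fibroblast-like clusters differed in fibrillar collagen level. Cluster 9, led by Cyp2f2 and Mfap4, held 32881 CPM (32632 to 33132), and cluster 7, led by Crabp1 and Dkk2, held 3244 CPM (3170 to 3320). Cluster 5, led by Mgp, a calcification inhibitor, was at 15549 CPM and cluster 3 at 9950 CPM. Pi16, a gene of adventitial fibroblasts, was at 1677 CPM in fibroblast-like cells, 39.2-fold (37.3 to 41.3) over the other cells, and Pdgfrb, a growth factor receptor, at 87.3 CPM.

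Gamma-delta T cell-like cells held Smad7, an inhibitor of TGF-beta signalling, at 327 CPM, 7.66-fold (6.08 to 9.54), and the tight junction gene Tjp1 at 251 CPM, 6.34-fold (4.86 to 8.13). In monocyte-like cells Ly6e was at 2391 CPM and Cxcl9, an interferon-induced chemokine, at 37.8 CPM, 6.56-fold (4.94 to 8.59). Hair follicle-like cells held Itgb8, an integrin chain that activates TGF-beta, at 57.5 CPM, 33.5-fold (26.1 to 43.0), and the small collagen Col8a2 at 31.9 CPM.

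Unnamed cluster 19, with 62 cells, had 8.43% mitochondrial UMIs and 1.10% ribosomal protein mRNA, against 2.44% and 26.9% in keratinocyte-like cells. Of the 97 skeletal muscle-like cells, 40 had 0 mitochondrial UMIs. Cycling cluster 15 made up 14.8% of the macrophage-like cells.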
